A study of Homo sapiens with 4 samples.

How the data were processed

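Gene expression was measured by RNA sequencing of total RNA from Hey-A8 cells, with 2 shCON libraries and 2 shSPTLC2 libraries, prepared with the NEBNext Ultra RNA kit per the labels' protocols. The labels conflict on the cells. Titles, genotypes and the design text describe a stable SPTLC2 knockdown with shCON as its control, whereas the treatment protocol describes hairpin plasmids against ZDHHC15 transfected transiently, with harvest at 36 h. The groups used here follow the titles, and both genes were reported in every library. The labels do not say whether replicates are separate cultures or whether equal replicate numbers mark a shared day.

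The deposited count table holds raw read counts, as whole numbers, for 58735 Ensembl genes in each library. The deposited FPKM table holds FPKM values that, checked within a relative tolerance of 1e-09, equal each count divided by the gene length in the table and by a library factor proportional to DESeq2's size factors. HISAT2, StringTie, SAMtools and build hg38 are listed per the submitters' processing notes, with no versions. The counting program and its strand setting are not given in the sources used here, so reads of antisense and overlapping genes cannot be told apart. Coordinates are those of the table, 1-based, on hg38. All 58735 gene IDs, symbols, starts and ends matched GENCODE 29 (Ensembl 94), which gave the transcript GC content of 15308 of the 15313 tested genes.

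Tests were run on the counts of all 4 libraries in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM, and the groups were compared by a robust quasi-likelihood fit and two-sided F test without covariates. Benjamini-Hochberg adjustment covered all tested genes, a gene was called at an adjusted p under 0.05, and the SE is the absolute log2 fold change over the square root of F. Log2 fold changes are shSPTLC2 over shCON, and CPM are counts scaled to TMM-adjusted library size. The common biological coefficient of variation was 10.1%. A count of changes by 2-fold or more is a count by size and not a test against that size.

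There were 34 gene lists with 870 members, all found in the table, fixed from general knowledge before the data were examined. The 32 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Camera called 10 lists, none of which was called with an estimated correlation (0 lists), while fry called 5 (cholesterol, ATF4, unfolded protein response, interferon and histones), each at an adjusted p of 0.043. With a correlation estimated from these 4 libraries, the unadjusted camera p of the 10 lists ran from 0.043 (cholesterol) to 0.42 (ribosomal proteins). Adjustment gave all 10 the same value, 0.62, which does not rank them. Fry tests whether a list's genes move on balance in one direction and does not compare them with other genes. Some genes belong to more than 1 list, SESN2, GADD45A and BIRC5 among them.

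The samples, comparisons, lists, alternatives and the rule for naming genes were also set before the data were examined. The rule named SPTLC2 and ZDHHC15. It also named the 12 coding genes with the largest rise and the 12 with the largest fall among called genes with a mean of at least 5 CPM and no overlap between groups, leaving out clone names. In each list it named up to 4 members with the smallest adjusted p and up to 2 with the highest mean CPM, and any member of the sphingolipid and AKT lists. List members named because a count was 5 or fewer lay outside the rule and were chosen after their values were seen. Some genes that the rule named are not reported here.

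Precision was judged from depth and from replicates. Total counts ran from 14464800 to 15085000 per library, and 3 counts in a library, the limit that a count of 0 allows, equal 0.195 to 0.206 CPM. Intervals and floors cover counting error only, and shares of counts carry exact 95% binomial intervals. The Pearson correlation of log2 CPM across genes, which are not independent replicates, was 0.987 between the shCON libraries, 0.990 between the shSPTLC2 libraries and 0.974 to 0.978 between groups. Between libraries of a group, 37.4% (shCON) and 28.7% (shSPTLC2) of genes had a chi-square p under 0.05, so neither pair is a single library deposited more than once. Deviations of libraries with the same replicate number had a correlation of -0.013 over all tested genes and -0.025 over 8227 abundant genes.

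The scripts were tested on simulated data, after a first look at the real comparison. With 200 genes changed among 15010 in simulated libraries of this comparison, edgeR recovered 46.3% of 1.5-fold, 71.6% of 2-fold and 97.0% of 4-fold changes, and 25 of 173 calls were unchanged genes. Camera called 0 of 34 random lists, and a planted list had an adjusted p of 8.6e-14. Genes were simulated independently, so these lists cannot show how camera treats lists of correlated genes. In the real data the estimated correlation was 0.59 for the mitochondrial list and -0.14 for the histone list. A simulated GC slope of 1.97 was reduced to 0.016 by the GC correction over 15000 genes.

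Other choices set beforehand were RLE, upper quartile and library total scaling, DESeq2 1.42.0, limma-voom, limma-trend on log2 FPKM with 1 or 0.1 added, no count filter, at least 1 CPM in 2 libraries, protein-coding genes only, replicate number as a block, a non-robust fit, and each library left out in turn. Further ones were an adjusted p under 0.01, glmTreat against a fold of 1.5, the estimated correlation and fry. A GC-content correction (lowess of each library's log2 CPM deviations on transcript GC, span 0.3) and the removal of mitochondrial genes were chosen after seeing the data. With a library left out, the lone library of its group is assumed to vary like the other group. FPKM values entered no main test, and columns of other samples in the tables numbered 0. Tables and figures also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and the R package data.table (version 1.17.8).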

Results

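RNA was sequenced from Hey-A8 cells, an ovarian cancer cell line, in 2 groups of 2 libraries. The shCON group carried a control hairpin and the shSPTLC2 group a hairpin labelled as directed at SPTLC2. Total counts, rounded to 6 digits, were 14999600 and 15017600 in shCON replicates 1 and 2 and 14464800 and 15085000 in shSPTLC2 replicates 1 and 2. Of 58735 genes in the table, 30392 had a count in any library and 15313 were tested. Every p-value here measures only the spread between these libraries, as nothing in the labels says that the replicates are separate cultures.

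SPTLC2 encodes a catalytic subunit of serine palmitoyltransferase, the enzyme that begins sphingolipid synthesis. SPTLC2 (ENSG00000100596, hg38 chromosome 14, 77505997 to 77616773) had 871 and 884 counts in shCON replicates 1 and 2 and 587 and 662 in shSPTLC2 replicates 1 and 2. Its mean was 59.7 ± 1.37 CPM (counts-per-million; SD, n = 2) in shCON and 41.5 ± 2.27 in shSPTLC2. Its log2 fold change was -0.52 ± 0.12 (SE; adjusted p = 0.0063, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Another 722 genes called lower had a more negative log2 fold change than SPTLC2. The call ended without shSPTLC2 replicate 1 (-0.47, adjusted p = 0.134) and without shSPTLC2 replicate 2 (-0.58, adjusted p = 0.052), and over the 18 alternatives the adjusted p by edgeR, DESeq2 or limma ran from 4.2e-04 to 0.134. ZDHHC15, the palmitoyltransferase gene that the treatment protocol names as the hairpins' target, is ENSG00000102383 in the table. ZDHHC15 had 0 counts in all 4 libraries, which allows up to 0.202 and 0.206 CPM in shCON replicates 1 and 2 and 0.204 and 0.195 CPM in shSPTLC2 replicates 1 and 2. No change of ZDHHC15 was detectable at this depth.

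**Figure D1:**
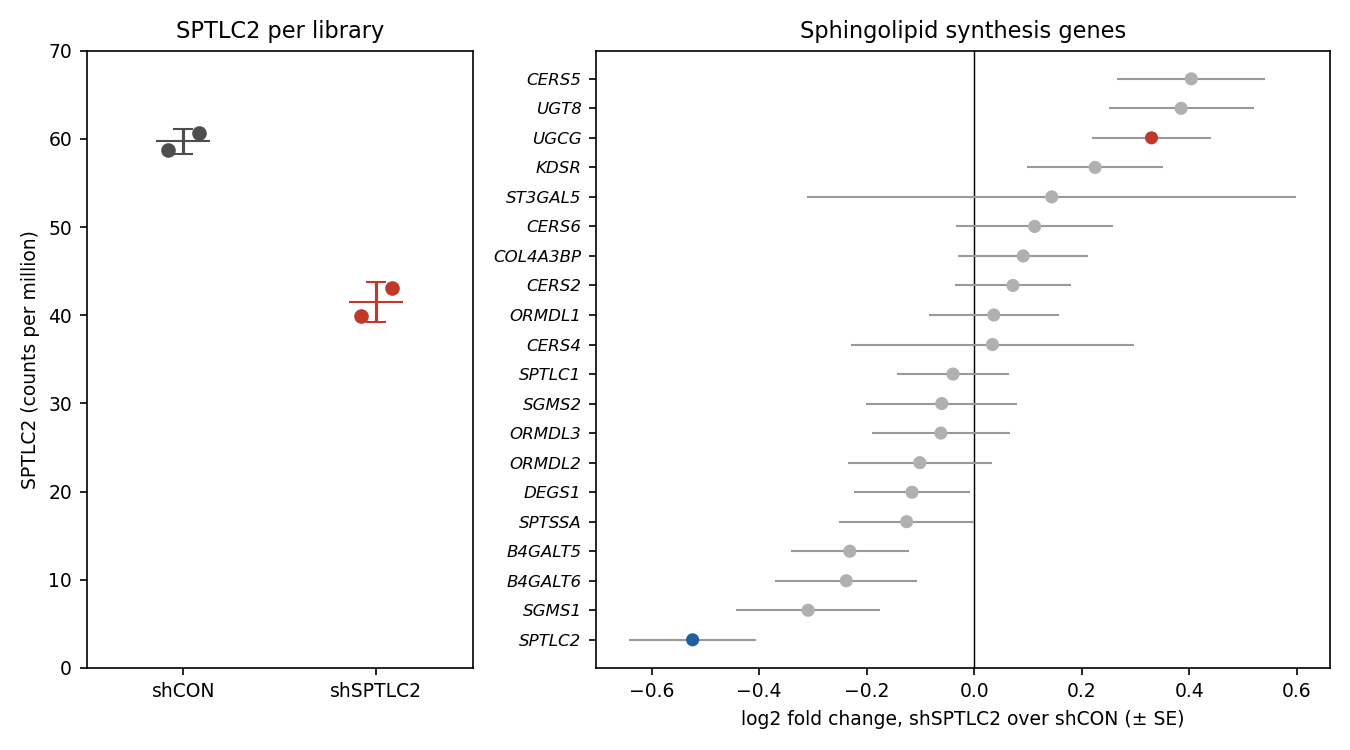
SPTLC2 in CPM per library (left; points are libraries, bars mean ± SD, grey shCON, red shSPTLC2) and log2 fold changes ± SE of 20 sphingolipid synthesis genes (right; red called higher, blue called lower, grey not called). SPTLC2 lay at 58.7 and 60.7 CPM in shCON and at 39.9 and 43.1 in shSPTLC2, and UGCG was the only other gene of the panel called.

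The comparison of shSPTLC2 with shCON asks which transcripts differ when the SPTLC2 hairpin is present. The cytokine gene IL24 (hg38 chromosome 1, 206897443 to 206904139) rose from 3.91 and 5.01 CPM in the shCON libraries to 15.4 and 26.6 CPM in the shSPTLC2 libraries, a log2 fold change of 2.23 ± 0.26 (SE). The cyclin gene CCND2 rose by 1.92 ± 0.28, the matrix glycoprotein gene EFEMP1 by 1.81 ± 0.17, the sterol transporter gene GRAMD1B by 1.73 ± 0.15, the death receptor gene TNFRSF25 by 1.67 ± 0.13 and the adhesion gene L1CAM by 1.62 ± 0.16. RELN (chromosome 7, 103471784 to 103989516), which encodes the secreted protein reelin, fell from 9.19 ± 0.789 to 1.13 ± 0.342 CPM (SD, n = 2), a log2 fold change of -3.01 ± 0.29. The adhesion gene AMIGO2 (chromosome 12, 47075707 to 47079951) changed by -2.03 ± 0.13, from 119.5 ± 11.6 to 29.3 ± 3.52 CPM. The guidance ligand gene SLIT2 (-1.64 ± 0.15), the growth factor gene HBEGF (-1.60 ± 0.11) and the stress gene SESN2 (-1.43 ± 0.11) fell too. Adjusted p in edgeR's quasi-likelihood test was lowest for AMIGO2 (6.7e-07) and HBEGF (1.0e-06), and it was 1.1e-05 for RELN and 3.1e-04 for IL24.

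The naming rule ranked only called coding genes with a mean of at least 5 CPM and no overlap between groups. The other genes among the 12 largest rises were GOLGA8B, GSDMB, GABBR1, HCN3, NPIPB12 and KLHL17, with log2 fold changes of 1.57 to 1.74. The other genes among the 12 largest falls were TRAF1, OAS2, HMGCS1, ZKSCAN2, POMK, IBA57 and KRCC1, with log2 fold changes of -1.65 to -1.46. Of these 24 genes, 23 were called whichever library was left out. NPIPB12 (adjusted p = 0.011 in edgeR) was not called without shSPTLC2 replicate 1 (adjusted p = 0.139, with a range over the alternatives of 1.4e-12 to 0.139). GOLGA8B and NPIPB12 have near-identical paralogs, so their counts are uncertain.

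**Figure D2:**
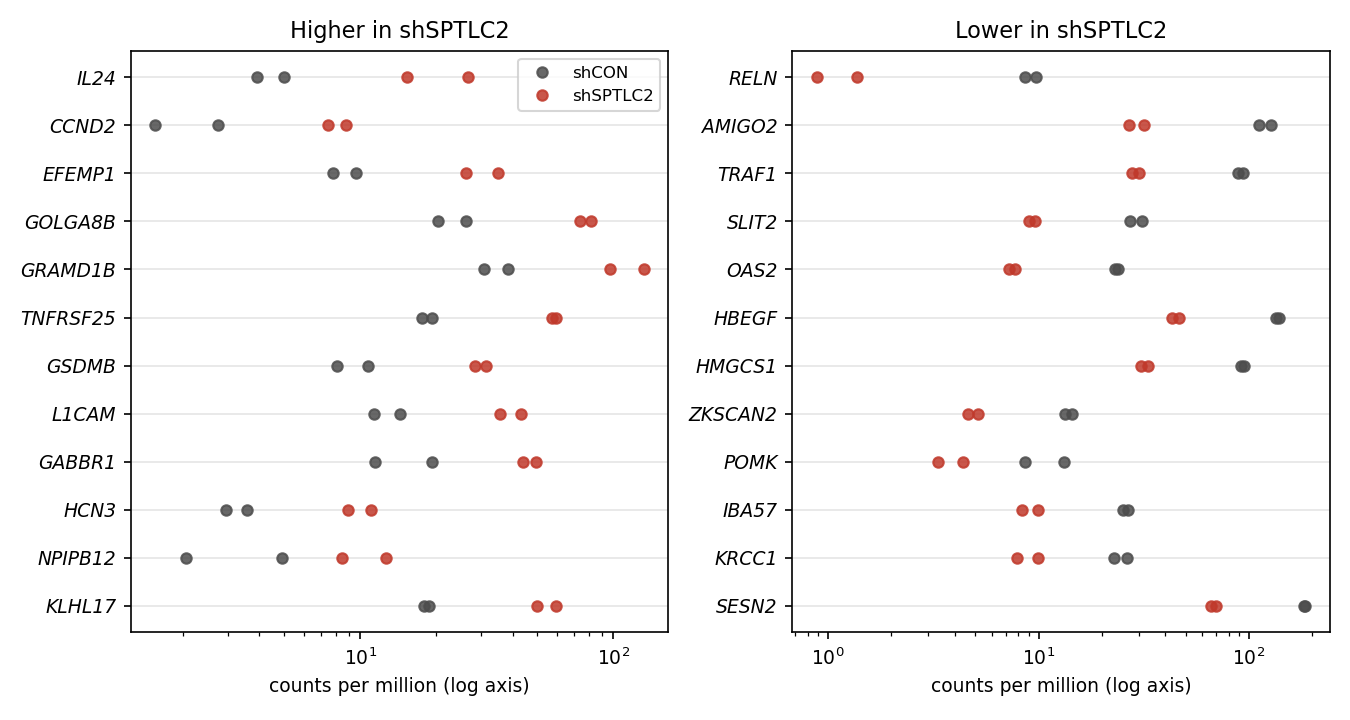
CPM (log axis) in each library for the 12 genes with the largest rise (left) and the 12 with the largest fall (right); each point is a library, grey shCON and red shSPTLC2. Only called coding genes with a mean of at least 5 CPM and no overlap between the 2 groups could be chosen. RELN fell from 8.63 and 9.75 CPM in shCON to 0.884 and 1.37 CPM in shSPTLC2.

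Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2971 of 15313 (19.4%), of which 1593 were higher and 1378 lower in shSPTLC2. The median fold size of the called genes was 1.52, and 560 changed by 2-fold or more (357 higher, 203 lower). Among 12547 protein-coding genes, 1382 were higher and 1276 lower. The libraries of the groups did not overlap for 61.5% of tested genes, against 33.3% by chance. Genes with GC-rich transcripts were more often higher: when coding genes were split into 5 equal groups by GC content, in the group with the highest content (58.4 to 74.8%) 586 were higher and 120 lower, against 162 and 359 in the middle group. The change with GC content was not a steady rise, as the group with the lowest content had 212 higher and 169 lower. After a GC-content correction 1399 genes were higher and 1566 lower, of which 1189 and 1465 were protein coding. With library totals in place of TMM, 65.1% of calls were higher, against 53.6% with TMM, and the median of all genes moved by 0.055 (log2). The number of calls fell to 640 without shSPTLC2 replicate 1 (413 higher, 227 lower; 276 by 2-fold or more, 175 higher and 101 lower) and to 994 without shSPTLC2 replicate 2 (593 higher, 401 lower; 347 by 2-fold or more, 226 higher and 121 lower). Without shCON replicate 1, 312 genes were lower by 2-fold or more.

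Among sphingolipid synthesis genes other than SPTLC2 only UGCG was called, while some breakdown and sphingosine-1-phosphate genes rose or fell. SPTLC1, which encodes the partner subunit, had a log2 fold change of -0.04 ± 0.10 (115.9 ± 0.874 CPM in shCON and 112.8 ± 1.15 in shSPTLC2). Of 20 synthesis genes tested, 1 rose (UGCG, 0.33 ± 0.11, which makes glucosylceramide), 1 fell (SPTLC2) and 18 were not called (0 and 1 adjusted over the list alone). Of 27 breakdown and sphingosine-1-phosphate genes, 2 rose, 3 fell and 22 were not called (2 and 3 adjusted over the list alone). The receptor genes S1PR3 (0.74 ± 0.16) and S1PR2 (1.01 ± 0.29) rose, while HEXA (-0.48 ± 0.13) and SGPP2 (-0.94 ± 0.27) fell. Neither list was called by camera (adjusted p = 0.81 and 0.65), and the synthesis list had a median of -0.003, a mean of 0.002 and a camera direction of lower. Leaving out either shSPTLC2 library ended the edgeR calls of UGCG (adjusted p = 0.15 and 0.42; 0.014 to 0.42 over the alternatives), HEXA (0.20 and 0.099; 0.0077 to 0.20), SGPP2 (0.062 and 0.22; 0.0017 to 0.22) and S1PR2 (0.14 and 0.13; 0.017 to 0.14). S1PR3 was not called without shSPTLC2 replicate 2 (0.11; 1.3e-05 to 0.11), SGPP2 without shCON replicate 2 (0.066) and S1PR2 without shCON replicate 1 (0.051). The synthesis list had 3 genes called higher and 2 lower without shCON replicate 1, 2 and 3 without shCON replicate 2, and 0 without either shSPTLC2 library.

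The series title ties SPTLC2 to the AKT pathway, so the genes of that pathway and its transcriptional targets were compared. Transcripts of the kinases were close to unchanged, with log2 fold changes of -0.09 ± 0.10 for AKT1 and 0.08 ± 0.10 for AKT2. Of 42 pathway genes, 2 rose (INPPL1, 0.64 ± 0.10, and TSC2, 0.45 ± 0.11), 3 fell (MTOR, -0.44 ± 0.11, FOXO3, -0.39 ± 0.12, and RPTOR, -0.34 ± 0.11) and 37 were not called (2 and 2 adjusted over the list alone). Of 20 FOXO targets, genes that AKT represses by way of FOXO factors, 3 rose, 6 fell and 11 were not called (4 and 6 adjusted over the list alone). RBL2 (0.68 ± 0.14), CCNG2 (0.80 ± 0.17) and CDKN1B (0.48 ± 0.12) rose, while TXNIP (-0.87 ± 0.12), CITED2 (-0.71 ± 0.11) and IGFBP1 (-1.30 ± 0.22) fell. Camera called neither list (adjusted p = 0.97 and 0.72), and the FOXO list had a median of 0.03, a mean of -0.04 and a camera direction of lower. Leaving out either shSPTLC2 library ended the edgeR calls of TSC2 (adjusted p = 0.087 and 0.14; 0.0018 to 0.14 over the alternatives), MTOR (0.19 and 0.085; 7.5e-05 to 0.19), FOXO3 (0.31 and 0.10; 0.0082 to 0.31), RPTOR (0.30 and 0.18; 0.011 to 0.30) and CDKN1B (0.13 and 0.098; 0.0049 to 0.13). RBL2 was not called without shSPTLC2 replicate 1 (0.053; 1.8e-07 to 0.053) and CCNG2 without shSPTLC2 replicate 2 (0.091; 3.5e-06 to 0.091). The AKT list had 6 genes called higher and 4 lower without shCON replicate 1, 3 and 5 without shCON replicate 2, and 1 and 0 without either shSPTLC2 library. The FOXO list had 5 and 6 without shCON replicate 1, 1 and 4 without shSPTLC2 replicate 1 and 1 and 5 without shSPTLC2 replicate 2.

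Many amino acid stress genes driven by ATF4 and cholesterol synthesis genes driven by SREBP2 were called lower in shSPTLC2. Of 29 ATF4 genes, 0 rose, 21 fell and 8 were not called (0 and 24 adjusted over the list alone), with a median of -0.48. SESN2, DDIT4 (-1.26 ± 0.11), ATF5 (-1.20 ± 0.16) and TRIB3 (-0.78 ± 0.11) fell. Of 25 cholesterol genes, 0 rose, 13 fell and 12 were not called (0 and 16 adjusted over the list alone), with a median of -0.55. HMGCS1 fell from 93.2 ± 2.71 to 31.8 ± 1.63 CPM (-1.55 ± 0.12), and ACAT2 (-1.03 ± 0.12) and INSIG1 (-0.94 ± 0.13) fell with it. Camera called both lists (adjusted p = 7.4e-09 for ATF4 and 7.4e-06 for cholesterol). With an estimated correlation, however, each had a camera adjusted p = 0.62 (unadjusted p = 0.052 for ATF4 and 0.043 for cholesterol). The number of ATF4 genes called lower was 9 without shSPTLC2 replicate 1 and 9 without shSPTLC2 replicate 2. The number of cholesterol genes called lower was 8 without shSPTLC2 replicate 1.

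Fatty acid synthesis genes went both ways, and some endoplasmic reticulum chaperone genes fell. Of 21 fatty acid genes, 3 rose, 4 fell and 14 were not called (4 and 4 adjusted over the list alone). DGAT1 (0.48 ± 0.13), DGAT2 (1.18 ± 0.38) and FADS1 (0.34 ± 0.11) rose, while ACLY (-0.45 ± 0.11), SCD (-0.40 ± 0.10), ACACA (-0.40 ± 0.12) and FASN (-0.41 ± 0.13) fell. Camera did not call this list (adjusted p = 0.72), which had a median of -0.04, a mean of 0.02 and a camera direction of lower. Without shSPTLC2 replicate 1, 0 of these 7 genes were called, and the edgeR adjusted p was highest there for ACACA (0.37; 7.3e-05 to 0.37 over the alternatives) and lowest for DGAT2 (0.14; 0.028 to 0.24). Without shSPTLC2 replicate 2 only 1 fatty acid gene was called. Calls also ended without shCON replicate 1 for FASN (-0.22, adjusted p = 0.12, over the alternatives 3.1e-07 to 0.28), DGAT2 (0.12) and FADS1 (0.14, over the alternatives up to 0.32), and without shCON replicate 2 for ACACA (0.094). Of 21 chaperone genes of the unfolded protein response, 0 rose, 7 fell and 14 were not called (0 and 8 adjusted over the list alone). HSPA5 (-0.66 ± 0.11) and HYOU1 (-0.45 ± 0.10) fell, and the median was -0.21. The chaperone list was called lower by fry (adjusted p = 0.043) and not by camera (adjusted p = 0.10). Without shSPTLC2 replicate 1, 0 chaperone genes were called, HSPA5 having an adjusted p of 0.071 in edgeR (3.7e-09 to 0.071) and HYOU1 of 0.15 (1.2e-05 to 0.15). Without shSPTLC2 replicate 2, 1 chaperone gene was called and HYOU1 was not (0.084).

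**Figure D3:**
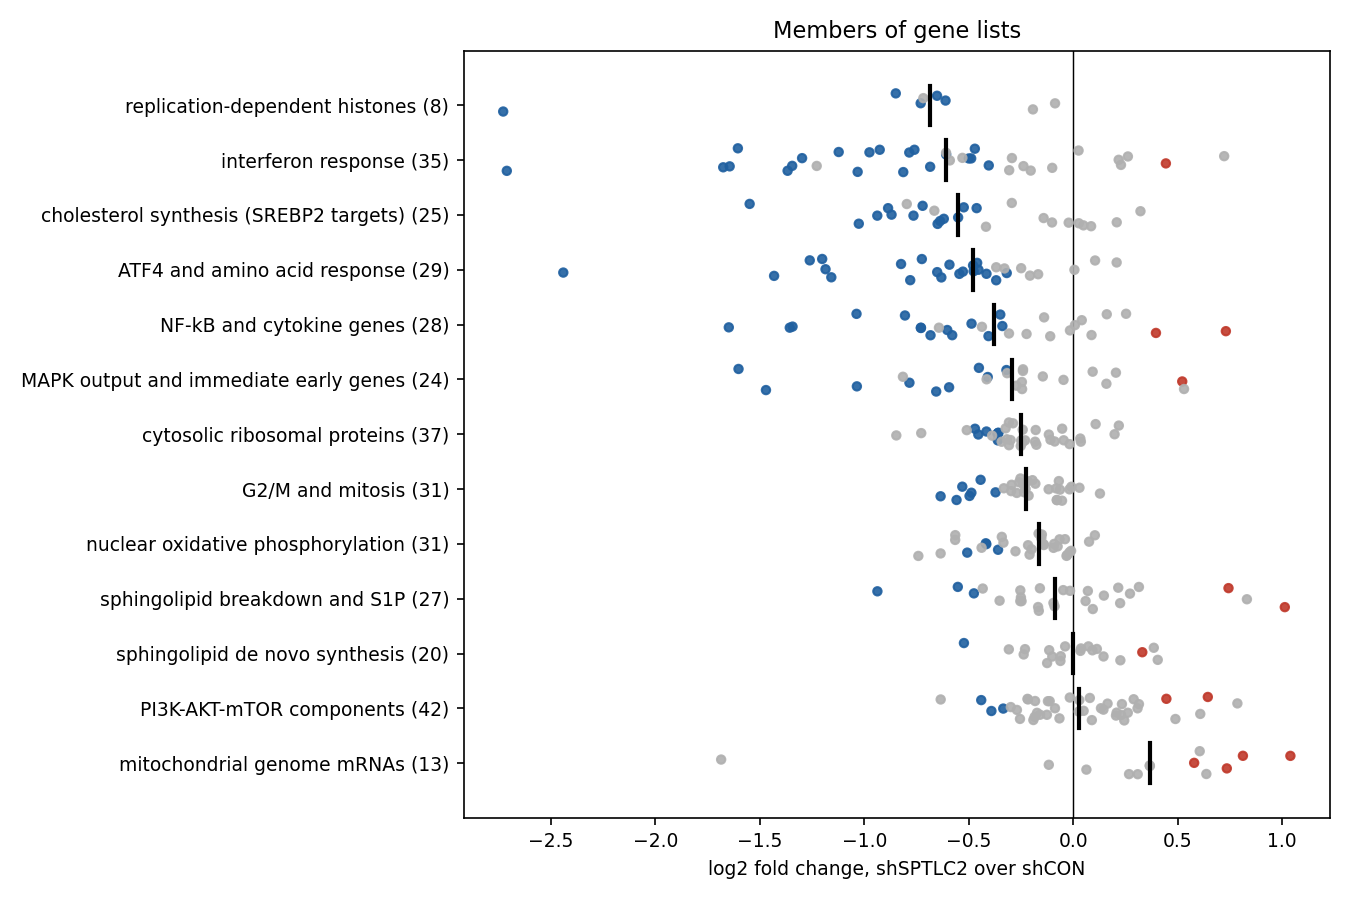
Log2 fold changes of tested members (points) of the 10 gene lists called by camera and of 3 sphingolipid and AKT lists, with the number tested in brackets; black bars are medians, red is called higher, blue called lower and grey not called. Medians ran from -0.69 (histones) to 0.37 (mitochondrial mRNAs), and those of the sphingolipid and AKT lists lay between -0.09 and 0.03.

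Many interferon-stimulated and NF-kB cytokine genes were called lower in shSPTLC2. Of 35 interferon genes, 1 rose (IFITM3, 0.44 ± 0.11), 20 fell and 14 were not called (1 and 23 adjusted over the list alone), with a median of -0.61. OAS2 (-1.64 ± 0.16), IFI44 (-1.12 ± 0.11), IFIT3 (-0.98 ± 0.12) and IFIT2 (-0.81 ± 0.11), all antiviral effectors, fell. Of 28 NF-kB and cytokine genes, 2 rose (IL11, 0.73 ± 0.15, and CXCL8, 0.40 ± 0.13), 14 fell and 12 were not called (2 and 16 adjusted over the list alone), with a median of -0.38. TRAF1 (-1.65 ± 0.12), CCL5 (-1.36 ± 0.18), TNFAIP3 (-1.04 ± 0.11) and ICAM1 (-0.81 ± 0.11) fell. Camera called both lists (adjusted p = 3.8e-07 for interferon and 8.2e-05 for cytokines). With an estimated correlation each had a camera adjusted p = 0.62 (unadjusted p = 0.078 for interferon and 0.14 for cytokines). In the fit without shSPTLC2 replicate 1, 11 interferon genes and 6 cytokine genes were called lower. Calls in edgeR ended for IFITM3 without shSPTLC2 replicate 1 (adjusted p = 0.15; 4.0e-06 to 0.15 over the alternatives) and replicate 2 (0.12), for CXCL8 without replicate 1 (0.066; 4.1e-04 to 0.53) and replicate 2 (0.53, at a log2 fold change of 0.19), and for IL11 without replicate 2 (0.087; 2.1e-04 to 0.087). IFITM3 has near-identical paralogs, so its counts are uncertain.

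Some growth factor response and mitotic genes were called lower, and replication genes went both ways. Of 24 MAPK output and immediate early genes, 1 rose (DUSP4, 0.52 ± 0.13), 9 fell and 14 were not called (1 and 9 adjusted over the list alone), with a median of -0.29. HBEGF and MYC (-0.78 ± 0.11) fell. Of 31 genes of G2/M and mitosis, 0 rose, 7 fell and 24 were not called (0 and 7 adjusted over the list alone), with a median of -0.23. PTTG1 (-0.64 ± 0.11) and CCNB1 (-0.56 ± 0.10) fell. Camera called the MAPK list (adjusted p = 6.6e-04) and the G2/M list (adjusted p = 7.9e-04). With an estimated correlation each had a camera adjusted p = 0.62 (unadjusted p = 0.23 for MAPK and 0.16 for G2/M). Of 31 genes of G1/S and replication, 2 rose (RRM2, 0.53 ± 0.15, and CCND3, 0.37 ± 0.12), 4 fell (TYMS, -0.66 ± 0.13, MCM2, MCM3 and MCM6) and 25 were not called (2 and 6 adjusted over the list alone; median -0.05, camera adjusted p = 0.50). In the MAPK list 2 genes were called lower without shSPTLC2 replicate 1, and 15 without shCON replicate 2. In the G2/M list 1 gene was called lower without shSPTLC2 replicate 1, 2 without shSPTLC2 replicate 2 and 12 without shCON replicate 2. None (0) of the 31 replication genes were called without shSPTLC2 replicate 1, and CCNB1 was not called without either shSPTLC2 library (adjusted p = 0.056 and 0.059 in edgeR; 3.0e-07 to 0.059 over the alternatives). The replication list had 3 genes called higher and 7 lower without shCON replicate 1, and 0 and 7 without shCON replicate 2. DUSP4 was not called without shSPTLC2 replicate 2 (0.28, adjusted p = 0.30; 3.7e-05 to 0.30), nor RRM2 without shCON replicate 2 (0.30, adjusted p = 0.062; 1.1e-08 to 0.26) or shSPTLC2 replicate 2 (0.081), nor CCND3 without these (0.18 and 0.15, over the alternatives up to 0.33).

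Of 26 p53 targets, 4 rose, 4 fell and 18 were not called (5 and 5 adjusted over the list alone). The antiproliferative gene BTG2 (1.21 ± 0.17), TP53INP1 (0.75 ± 0.15), FDXR (0.54 ± 0.12) and MDM2 (0.45 ± 0.11) rose, while SESN2, GADD45A (-0.69 ± 0.11), XPC (-0.76 ± 0.14) and AEN (-0.35 ± 0.11) fell. The p53 list had a median of 0.16 and was not called by camera (adjusted p = 0.75), whose direction was higher while that of fry was lower. Of 33 apoptosis regulators, 2 rose (BOK, 0.60 ± 0.12, and APAF1, 0.59 ± 0.16), 3 fell (PMAIP1, -0.92 ± 0.11, BIRC5 and BIRC3) and 28 were not called (2 and 3 adjusted over the list alone; median -0.11, camera adjusted p = 0.29). BTG2, SESN2, GADD45A and PMAIP1 were called whichever library was left out. Without shSPTLC2 replicate 1, 2 p53 targets were called higher and 2 lower, against 1 and 3 without shSPTLC2 replicate 2 and 9 and 6 without shCON replicate 1. Of the apoptosis list 3 genes were called higher without shCON replicate 1, 5 lower without shCON replicate 2, and 1 higher and 1 lower without either shSPTLC2 library. The p53 median was 0.08 and the apoptosis median -0.04 without shSPTLC2 replicate 2, and the apoptosis median was -0.17 without shCON replicate 1. The log2 fold change of TP53INP1 was 0.49 without shSPTLC2 replicate 2 (adjusted p = 0.10 in edgeR; 2.3e-06 to 0.10 over the alternatives), and that of APAF1 was 0.36 (adjusted p = 0.28; 0.0019 to 0.28). BOK was not called without shSPTLC2 replicate 1 (0.10; 1.1e-07 to 0.10), nor XPC (0.061; 7.2e-08 to 0.061). FDXR, MDM2, AEN, BIRC5 and BIRC3 were not called without either shSPTLC2 library, with edgeR adjusted p of up to 0.10, 0.13, 0.23, 0.26 and 0.38 over the alternatives, and AEN was not called without shCON replicate 2 (0.11).

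Of 33 genes for matrix proteases and motility, 3 rose (ITGB4, 1.91 ± 0.37, MMP15, 0.83 ± 0.16, and TIMP2, 0.43 ± 0.11), 9 fell and 21 were not called (3 and 9 adjusted over the list alone; median -0.11, camera adjusted p = 0.058). The matrix list was called by camera without shCON replicate 2 (adjusted p = 0.019) and without shSPTLC2 replicate 2 (0.014), with a range of 0.012 to 0.62 over the alternatives. It was not called without shCON replicate 1 (0.31, median -0.03) or shSPTLC2 replicate 1 (0.24, median -0.01), and the median was -0.19 without shCON replicate 2 and -0.17 without shSPTLC2 replicate 2. The proteases ADAMTS1 (-1.11 ± 0.10), PLAU (-0.95 ± 0.11) and MMP2 (-1.29 ± 0.23) fell. Of 25 mesenchymal genes, 2 rose (COL5A1, 1.08 ± 0.11, and COL1A1, 1.52 ± 0.30), 1 fell (ZEB2, -0.40 ± 0.13) and 22 were not called (2 and 0 adjusted over the list alone). This list had a median of -0.03, a mean of 0.06 and a camera direction of higher (adjusted p = 0.87), and VIM, at 4743 ± 440 CPM in shCON, changed by -0.19 ± 0.12. Of 13 epithelial and Mullerian markers tested, 2 rose (PAX8, 0.73 ± 0.11, and MSLN, 0.61 ± 0.16), 0 fell and 11 were not called (2 and 0 adjusted over the list alone; median 0.29, camera adjusted p = 0.20). CDH1 had 0 counts in all 4 libraries. Without shSPTLC2 replicate 1, 1 matrix gene was called higher and 3 lower, and calls in edgeR ended for MMP15 (adjusted p = 0.074; 1.3e-04 to 0.074 over the alternatives), TIMP2 (0.11; 1.2e-05 to 0.18), COL1A1 (0.069; 2.2e-05 to 0.069), ZEB2 (0.34; 0.014 to 0.34) and MSLN (0.12; 0.0047 to 0.17). Without shSPTLC2 replicate 2, calls ended for ITGB4 (0.067; 7.7e-06 to 0.067), TIMP2 (0.18), ZEB2 (0.10) and MSLN (0.13). Without either shCON library 6 mesenchymal genes were called higher, and without shCON replicate 1 so were 4 epithelial markers. The median of the epithelial markers was 0.45 without shCON replicate 1, 0.14 without shCON replicate 2, 0.18 without shSPTLC2 replicate 1 and 0.16 without shSPTLC2 replicate 2.

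Of 23 YAP-TEAD targets, 1 rose (ARHGEF17, 0.55 ± 0.12), 5 fell (NT5E, -0.81 ± 0.11, MYOF, -0.58 ± 0.12, AMOTL2, IGFBP3 and ANKRD1) and 17 were not called (1 and 5 adjusted over the list alone; median -0.01, camera adjusted p = 0.26). Of 20 TGF-beta targets, 1 rose (PMEPA1, 1.16 ± 0.18), 2 fell (SMAD7, -1.10 ± 0.13, and ID1, -0.34 ± 0.11) and 17 were not called (1 and 2 adjusted over the list alone; median 0.15, camera adjusted p = 0.31). Of 31 hypoxia and glycolysis genes, 3 rose (ENO2, 0.47 ± 0.11, P4HA2 and MXI1), 5 fell (HK2, -0.57 ± 0.11, PKM, -0.58 ± 0.12, VEGFA, PGK1 and ENO1) and 23 were not called (3 and 5 adjusted over the list alone; median -0.05, camera adjusted p = 0.35). Of 21 NRF2 and oxidative stress genes, 3 rose (GCLM, 0.67 ± 0.14, HMOX1, 0.64 ± 0.13, and ABCC3), 4 fell (AKR1C1, -1.20 ± 0.12, TXNRD1, -0.58 ± 0.11, PGD and GCLC) and 14 were not called (3 and 6 adjusted over the list alone; median -0.26, camera adjusted p = 0.26). Of 29 autophagy and lysosome genes, 2 rose (TFEB, 1.91 ± 0.28, and CTSD, 0.56 ± 0.12), 6 fell, SQSTM1 (-1.01 ± 0.11) among them, and 21 were not called (2 and 6 adjusted over the list alone; median -0.01, camera adjusted p = 0.36). NT5E, SMAD7, PMEPA1, AKR1C1, SQSTM1 and TFEB were called whichever library was left out. Without shSPTLC2 replicate 1, the members called higher and lower were 0 and 2 YAP-TEAD, 1 and 1 TGF-beta, 0 and 0 hypoxia, 1 and 1 NRF2 and 1 and 1 autophagy genes. Without shSPTLC2 replicate 2 they were 1 and 2, 1 and 1, 0 and 1, 1 and 2, and 2 and 3. Without shCON replicate 1 they were 3 and 8, 4 and 2, 4 and 9, 4 and 5, and 4 and 7, and without shCON replicate 2 they were 2 and 4, 3 and 3, 3 and 6, 3 and 5, and 2 and 7. The NRF2 median was -0.14 without shCON replicate 1, -0.09 without shSPTLC2 replicate 1 and -0.12 without shSPTLC2 replicate 2. The TGF-beta median was 0.07 without shSPTLC2 replicate 2 and 0.23 without shSPTLC2 replicate 1, the hypoxia median -0.11 without shCON replicate 2 and -0.13 without shSPTLC2 replicate 2, the autophagy median -0.13 and the YAP-TEAD median -0.08 without shCON replicate 2. Calls in edgeR ended without shCON replicate 1 for ABCC3 (adjusted p = 0.075) and without shCON replicate 2 for ANKRD1 (0.053) and MXI1 (0.15), with values up to 0.19, 0.19 and 0.42 over the alternatives. AKR1C1 has near-identical paralogs, so its counts are uncertain.

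Some ribosomal protein, respiratory chain and histone genes were called lower, and some mitochondrially encoded genes higher. Of 37 cytosolic ribosomal protein genes, 0 rose, 7 fell and 30 were not called (0 and 7 adjusted over the list alone), with a median of -0.25, and RPS6 fell by 0.47 ± 0.13. Of 31 nuclear genes of oxidative phosphorylation, 0 rose, 4 fell (UQCRFS1, -0.51 ± 0.11, NDUFS3, -0.42 ± 0.12, ATP5F1B and COX6C) and 27 were not called (0 and 4 adjusted over the list alone), with a median of -0.17. Of 13 mitochondrially encoded mRNAs, 4 rose (MT-CO1, 1.04 ± 0.14, MT-ND4, 0.81 ± 0.13, MT-CYB, 0.58 ± 0.13, and MT-ND5, 0.73 ± 0.19), 0 fell and 9 were not called (5 and 0 adjusted over the list alone), with a median of 0.37. Mitochondrial genes took 5.46% and 6.39% of counts in shCON replicates 1 and 2 and 10.1% and 8.56% in shSPTLC2 replicates 1 and 2, with exact 95% binomial intervals, which cover counting error only, of 5.45 to 5.47%, 6.38 to 6.40%, 10.05 to 10.08% and 8.55 to 8.57%. Of 15 members of the histone list, only 8 had enough counts to be tested, all replication-dependent but H1F0 (-0.09, not called). The untested members had at most 11 counts in any library, so the list covers only those histone transcripts that these libraries read. Of these 8 genes, 0 rose, 5 fell and 3 were not called (0 and 5 adjusted over the list alone), with a median of -0.69. Those that fell were HIST1H2AC (-0.73 ± 0.14), HIST1H2BC (-2.73 ± 0.52), HIST1H2BK, HIST2H2BE and HIST1H1C. Camera called the ribosomal (adjusted p = 0.0012), respiratory (0.011), mitochondrial (0.013) and histone (0.0012) lists. With an estimated correlation each had a camera adjusted p = 0.62 (unadjusted p = 0.42, 0.23, 0.40 and 0.064 in the same order). Histone genes, ribosomal protein genes and overlapping mitochondrial genes share sequence, so their counts are uncertain.

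Leaving out single libraries moved several of these last lists. Camera did not call the mitochondrial list without shCON replicate 1 (adjusted p = 0.36; 4.1e-05 to 0.62 over the alternatives) or without shSPTLC2 replicate 1 (0.12), the histone list without shCON replicate 1 (0.071; 3.3e-04 to 0.62; its median was -0.65 there), or the respiratory list without shCON replicate 2 (0.17; 2.9e-04 to 0.62) or without shSPTLC2 replicate 1 (0.059). The median of the ribosomal list was -0.41 without shCON replicate 1, where 27 genes were called lower, and -0.08 without shCON replicate 2, where 4 were. The respiratory list had 13 genes called lower and a median of -0.27 without shCON replicate 1, and a median of -0.09 without shCON replicate 2. The mitochondrial list had 6 genes called higher, 2 lower and a median of 0.14 without shCON replicate 1, against 11 higher and a median of 0.62 without shCON replicate 2 and 2 higher without shSPTLC2 replicate 1. Without either shSPTLC2 library 0 ribosomal and 0 respiratory genes and 2 histone genes were called. The log2 fold change of HIST1H2BC was -4.22 without shSPTLC2 replicate 2, and that of RPS6 was -0.29 without shCON replicate 2. Calls in edgeR ended without shSPTLC2 replicate 1 for MT-CYB (adjusted p = 0.17; 4.2e-09 to 0.26 over the alternatives), MT-ND5 (0.20; 3.5e-21 to 0.20) and HIST1H2BC (0.053; 1.9e-06 to 0.053), and without shSPTLC2 replicate 2 for MT-ND5 (0.087) and HIST1H2BK (0.096, its highest). In limma on log2 FPKM, MT-CO1 and MT-ND4 were not called (adjusted p up to 0.19 and 0.18). Without shCON replicate 2 edgeR calls ended for COX6C (0.26) and HIST1H1C (0.22), each with values up to 0.27 over the alternatives.

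Other palmitoyltransferase genes and markers of other cells were compared because of the ZDHHC15 wording and as a check on the cells. Of 20 ZDHHC genes, 3 rose (ZDHHC8, 1.03 ± 0.12, ZDHHC9, 0.56 ± 0.13, and ZDHHC21, 0.40 ± 0.13), 0 fell and 17 were not called (5 and 0 adjusted over the list alone; median 0.23, camera adjusted p = 0.057). Camera called the ZDHHC list without shSPTLC2 replicate 2 (adjusted p = 0.035) but not without shSPTLC2 replicate 1 (0.25, median 0.11), shCON replicate 2 (0.17, median 0.14) or shCON replicate 1 (0.078), with a range of 0.0135 to 0.62 over the alternatives. Of 13 genes that process hairpins, 0 rose, 1 fell (TNRC6C, -0.49 ± 0.16) and 12 were not called (0 and 0 adjusted over the list alone; median -0.06, camera adjusted p = 0.35). Of 6 tested members of the list of unspliced and nuclear RNAs, 0 were called over all genes and 0 adjusted over the list alone (median 0.17, camera adjusted p = 0.81). NEAT1 changed by 0.60 ± 0.31 and MALAT1 by 0.20 ± 0.19. RN7SL2, GAS5 and SNHG1, which are not markers of nuclear RNA, were members too, so the median does not measure nuclear RNA. The median of this mixed list depended on single shCON libraries: it was -0.14 without shCON replicate 1 and 0.46 without shCON replicate 2. In the ZDHHC list 5 genes were called higher without shCON replicate 1 and 1 without shSPTLC2 replicate 1, and in the hairpin list 1 higher and 2 lower without shCON replicate 1. Of 8 endothelial markers, 2 rose (CDH5, 1.09 ± 0.12, and ESAM), 1 fell (PECAM1) and 5 were not called (2 and 1 adjusted over the list alone; median -0.08, camera adjusted p = 0.67). Of 6 fibroblast and pericyte markers, 1 rose (MCAM, 0.63 ± 0.11), 2 fell (FAP, -0.86 ± 0.19, and CSPG4) and 3 were not called (1 and 3 adjusted over the list alone; median -0.38, camera adjusted p = 0.26). The only leukocyte marker tested, CD8A, was not called (-0.40 ± 0.42), and of 3 markers of other epithelial lines 0 were called over all genes and 0 adjusted over the list alone. Calls in edgeR ended without shSPTLC2 replicate 1 for ZDHHC9 (adjusted p = 0.078; 0.0014 to 0.078 over the alternatives), ZDHHC21 (0.21; 0.0023 to 0.29), TNRC6C (0.17; 0.0021 to 0.23), ESAM (0.32; 0.0020 to 0.32), PECAM1 (0.21; 0.0065 to 0.21), FAP (0.089; 7.7e-04 to 0.089) and CSPG4 (0.32; 9.7e-04 to 0.32). Without shSPTLC2 replicate 2 MCAM was not called (0.055; 2.5e-07 to 0.055), nor were ZDHHC9 (0.077), ZDHHC21 (0.21), TNRC6C (0.23), ESAM (0.062), PECAM1 (0.054) and FAP (0.0502). Without shCON replicate 2 ZDHHC21 (0.17), TNRC6C (0.18) and ESAM (0.11) were not called, nor PECAM1 without shCON replicate 1 (0.054). The median of the fibroblast and pericyte markers was 0.002 without shCON replicate 1, and that of the endothelial markers was -0.20 without shCON replicate 2 and -0.18 without shSPTLC2 replicate 2.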

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

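No test in this part was chosen after the result was seen except the GC-content correction and the removal of mitochondrial genes. SPTLC2 stayed lower under all 18 alternatives (-0.58 to -0.45) and was called in 15 of them. It was not called by limma on log2(FPKM + 1) (-0.45, adjusted p = 0.051) or without shSPTLC2 replicate 1 (-0.47, adjusted p = 0.134) or shSPTLC2 replicate 2 (-0.58, adjusted p = 0.052). Over the 4 fits with a library left out it ran from -0.58 to -0.47 and its adjusted p from 4.2e-04 to 0.134. ZDHHC15, at 0 counts in every library, has no value under any alternative.

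Leaving out 1 library gave 640 to 4027 changed genes (413 to 1977 higher, 227 to 2050 lower) and 276 to 732 changed by 2-fold or more (175 to 432 higher, 101 to 312 lower). The lowest came without shSPTLC2 replicate 1 and the highest without shCON replicate 1, except that 432 came without shCON replicate 2. Each of these fits leaves out a single library, so the number of samples does not set them apart. Without a shSPTLC2 library the spread came from the shCON pair, and without a shCON library from the shSPTLC2 pair. The shCON pair differed more (chi-square per gene 15.06, against 6.343 in the shSPTLC2 pair). Whether this alone accounts for the lower counts was not tested. Of the 2971 genes, 634 were called without shSPTLC2 replicate 1 and 966 without shSPTLC2 replicate 2.

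DESeq2 called 1978 genes (972 higher), and 329 by 2-fold or more (209 higher, 120 lower). Limma-trend called 1450 genes (761 higher, 689 lower) on log2(FPKM + 1) and 1397 (738 higher, 659 lower) on log2(FPKM + 0.1). With 1 added, which shrinks changes of weakly expressed genes, 112 changed by 2-fold or more (72 higher, 40 lower). For DESeq2 and limma the cause was not tested. By construction, an adjusted p under 0.01 left 1295 genes (756 higher, 539 lower), and glmTreat against a fold of 1.5 left 188 (118 higher, 70 lower). DESeq2 kept 1941 of the 2971 genes, limma-voom 2729, RLE 2935, library totals 2625, the GC-content correction 2487 and the removal of mitochondrial genes 2949. Of the 2971 genes, 0 changed sign under an alternative that gave them a value. With library totals 65.1% of calls were higher, against 53.6% with TMM. The replicate block called 3307 genes and kept 2954 of the 2971, with SPTLC2 at -0.52 (adjusted p = 0.0020).

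Camera called 8 to 14 lists under the other alternatives (8 to 12 with a library left out), 0 with an estimated correlation and 5 with fry. The non-robust fit does not apply to list tests, and the mitochondrial list has no value when its genes are removed. Among results for single lists and named genes other than SPTLC2 over all alternatives, 410 lost a call, 82 gained one and 0 reversed. The other 4131 kept their side of the threshold. They include results called neither in the main test nor in the alternative, so they do not measure how many calls held. In data simulated at this depth with 2 libraries per group, 46.3% of 1.5-fold changes were recovered, and depth was not varied. The simulated data had far fewer changed genes than were called in the real data, so this share may not carry over. At this depth 0 counts, as of ZDHHC15, allow up to 0.206 CPM.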

Other observations

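The tests of the 4 lowered lists and of the GC trend on chromosome 21 were chosen only after the result was seen, and the other tests were set out before their results. Bounds of some of these tests were loosened after the values were seen and then returned to their first form, which decides each test below. Comparisons with 0 for the cytokine list and for chromosome 21 without list members were added after the values were seen. The scaling test was divided by list after its values were seen. Chromosome 21 was picked because its median was the lowest of 23 chromosomes compared. Of its 118 coding genes tested, 5 were higher and 32 lower, with a median log2 fold change of -0.20 (SE 0.053), and 66.9% of its genes lay below 0. Their summed abundance was 8629 and 8607 CPM in the shCON libraries and 7214 and 7443 CPM in the shSPTLC2 libraries. The superoxide dismutase gene SOD1 changed by -0.45, the amyloid precursor gene APP by -0.41, ETS2 by -0.46 and HMGN1 by -0.41, and these genes were chosen after their values were seen.

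RNA classes were counted and not tested against each other. Of 131 sense intronic genes 14 were higher and 0 lower (median 0.25, SE 0.053), and after the GC-content correction the median was 0.14 (SE 0.074) with 14 higher. Of 426 processed pseudogenes 10 were higher and 31 lower. The sense intronic class had been set out as a pattern to weigh and was replaced by chromosome 21 once its values were seen. Reads in 381 olfactory receptor genes, which these cells should not transcribe, came to 2.83 and 2.95 CPM in shCON and 2.24 and 2.48 CPM in shSPTLC2. The ratio was 0.817 (95% counting interval 0.588 to 1.13). No rise was seen, but the interval includes 1 and covers counting error only. A small rise in genomic DNA in the shSPTLC2 libraries therefore cannot be excluded.

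Lower chromosome 21 expression may reflect the GC trend, members of the lowered lists, or fewer copies of the chromosome in part of the shSPTLC2 cells. The GC trend is argued against, as the median was -0.23 (SE 0.061) after the correction, with 3 genes higher and 37 lower. Without members of the lowered lists the median over 114 genes was -0.18 (SE 0.050), and 30 of the 32 lower genes remained. The bound set beforehand, a median plus 2 SE below -0.1, was not met, so by that bound the test did not decide. The median of these 114 genes still lay below 0 by more than 2 SE, which argues against list members as the whole cause. Fewer copies stay open: the medians by position were -0.23 (SE 0.060), -0.12 (SE 0.114) and -0.13 (SE 0.093). Only that of the part from 5022493 to 33480011 was below 0 by more than 2 SE.

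The ATF4, cholesterol, interferon and cytokine lists were lower, and the GC trend, library scaling and lower mTORC1 output downstream of AKT are candidate explanations. After the GC correction the highest of the 4 medians was -0.43, each staying below -0.1 by more than 2 SE, which argues against the GC trend as the whole cause. Under 4 other scalings the highest median of the ATF4, cholesterol and interferon lists was -0.43, which argues against scaling for those 3. For the cytokine list, library totals moved the median from -0.38 to -0.32. The median plus 2 SE, -0.09, fell short of the bound of -0.1, so by that bound the test did not decide. Library totals moved the median of all genes by only 0.055, and the cytokine median stayed below 0 by more than 2 SE under all 4 scalings. These values argue against scaling as the whole cause for this list. Lower mTORC1 output would also lower the fatty acid and glycolysis lists, and camera called neither (adjusted p = 0.72 and 0.35). The outcome set against it, both lists higher, would not follow from its absence. The test therefore could not exclude lower mTORC1 output, which cannot be told apart from its absence.

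Genes with GC-rich transcripts were higher, which might come from GC-dependent recovery of fragments in library preparation or from more unspliced or nuclear RNA. The slope of log2 fold change on GC was 0.988 (SE 0.051) over coding genes and -0.046 (SE 0.171) over noncoding genes. Within groups the coding slope was 0.116 (SE 0.036) between the shCON libraries and -0.438 (SE 0.031) between the shSPTLC2 libraries, at most 0.456 of the 0.960 between groups on the same log2 CPM scale, short of the 0.5 that recovery of fragments was held to need. The noncoding slope was not above 0 either, so neither condition set for recovery of fragments was met. Recovery of fragments stays open, since the noncoding slope was not below 0 by more than 2 SE, the bound set against it. That slope also varied within groups by more than its SE. It was 0.933 (SE 0.157) between the shCON libraries and -0.283 (SE 0.130) between the shSPTLC2 libraries. More nuclear RNA stays open as well, as NEAT1 changed by 0.60 (SE 0.31) and MALAT1 by 0.20 (SE 0.19), neither beyond 2 SE. Sense intronic genes took 0.031% and 0.032% of counts in shCON replicates 1 and 2. In shSPTLC2 replicates 1 and 2 they took 0.043% and 0.041%, a direction that more unspliced RNA would give. This share was not tested, and the median of these genes was 0.14 (SE 0.074) after the GC correction. Over the alternatives NEAT1 ran from 0.23 to 1.07 and MALAT1 from -0.10 to 0.56. No biological explanation was tested.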
